A study of Homo sapiens with 4 samples.

How the data were processed

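Total RNA from the glioblastoma lines U251 and U87 was profiled on 4 one-colour Agilent arrays, 1 each for U251 with GFP, U251 with PINT87aa, U87 with GFP and U87 with PINT87aa. Per the labels' protocols, the reading frame of GFP or PINT87aa was cloned into a lentiviral psin-EF2 vector, infected cells were kept under puromycin (2 µg/ml) for 72 h, TRIzol was used to extract the RNA, and Cy3-labelled cRNA was made from 1 µg of RNA. Per the file headers the 4 arrays lay on 1 slide and were read in 1 scan, so no slide or scan batch separates them, while position on the slide and group cannot be told apart. The sources do not say whether the arrays come from separate cultures.

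Per the file headers and the submitters' processing notes, the authors read the slide with Agilent Feature Extraction 11.0.1.1. Each deposited array file holds the processed signal as an intensity, background-subtracted and spatially detrended, not scaled between arrays, for 44495 spots. The deposited raw median signal and its local background are intensity values without any scaling. Per the file headers, the deposited spot flags (well above background, saturated, non-uniform outlier, population outlier) are other values of 0 or 1. The deposited series table holds log2 values; its columns correlated above 0.999 with log2 of the processed signal and their sorted values differed by at most 0.0040, so from the values it is quantile-normalised between the arrays and not centred. The sources do not state that step. The headers name build hg19 for the design, and no coordinates are given here.

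Control spots and spots with an outlier flag (243 to 304 per array) were left out; 0 spots were saturated. The processed signal of the kept spots, out of 43118 non-control spots, was averaged for each of 34127 probes. The log2 of this mean minus its 75th percentile over the array's probes was the value used. Probe accessions were matched to the RefSeq gene table of assembly GRCh38.p14, used for names only: 25771 probes matched 19740 symbols and 8356 had no match. A gene with several probes took the one with the highest mean among those well above background on at least 1 array. A gene entered a line's count when well above background on at least 1 of the line's 2 arrays and was counted at a log2 difference of 1, that is 2-fold. For a gene dim on 1 array with every probe, the fold is a lower bound against the lowest value well above background on that array.

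The construct effect over both lines and the line difference were fitted with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8), with line and construct as terms, 1 residual degree of freedom, eBayes with trend and a prior of 20.5 degrees of freedom, on 15558 genes well above background on at least 2 arrays; calls are adjusted p under 0.05 (Benjamini-Hochberg), two-sided. The crossed split, the only other one that parts both pairs, was the reference, although it is the residual of the construct fit and so not independent of it. In all, 36 gene lists were fixed together with the rule for named genes before the data were examined. Of 629 members 626 matched a symbol, 22 through an older symbol, and 615 had a probe. Lists with at least 4 measured members were compared in each line with 10000 random lists drawn within 20 expression bins and tested over both lines with camera (preset correlation 0.01) and fry, adjusted over 34 lists. Fry tests whether a list's genes move, on balance, one way. The lists of endothelial markers and of the LINC-PINT locus were too small for a test.

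The rule for named genes took, in each line, the 12 genes per direction with the largest difference among those above background on both arrays, up to 4 per direction above background on 1 array, the 10 per direction with the largest shared difference and 5 per sign in opposite ways, the limma calls, the 10 largest line differences per direction, all members of the PAF1, LINC-PINT and authors' lists and up to 4 members of each other list; clone names were left out. On simulated data for the construct effect (15558 genes), limma recovered 31% of genes changed by a log2 of 1 and 99% of those changed by 2, with 25 false calls. In a simulation of the U251 pair (15621 genes), 3.5% of unshifted lists of 20 lay outside the random range and 98% of those shifted by 0.3.

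Alternatives, one at a time, were normexp background (offset 50, on the median signal, since the mean signal is not a column of the files), quantile, cyclic loess and median scaling, the deposited series table, outlier spots kept, other filters on dim probes, the mean of all probes, a 1.5-fold threshold, no block, trend = FALSE, unmatched random lists, an estimated correlation and fry. Random seeds were fixed, at 1 for the random lists and the random sets of spots and at other values for the simulations. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. A comparison of long with short genes was run and left out, because the gene table comes from another build than the one the headers name. Probes without a symbol were counted but are not named.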

Results

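Gene expression was measured in U251 and U87, established human glioblastoma cell lines. Each line had been made to carry either the open reading frame of PINT87aa or GFP as the control, giving 4 groups with 1 array each. PINT87aa is a small peptide encoded by a circular RNA of the LINC-PINT locus, and the arrays were made to look for its regulatory role, with cell cycle, apoptosis and oncogenic signalling named as its fields. Signal stood well above background for 67.6% of probes on the U251 GFP array, 73.3% on the U251 PINT87aa array, 64.6% on the U87 GFP array and 71.1% on the U87 PINT87aa array. The 75th percentile of the processed signal was 1902.57, 2354.33, 1064.21 and 2054.33 intensity units on the same arrays. Because each group had 1 array, differences within a line have no p-value and are given as PINT87aa minus GFP on the log2 scale. The SD over replicate spots of a probe was 0.158 for a U251 difference and 0.138 for a U87 difference; it covers spot noise only. The number of arrays limits the precision of every value.

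In U251 cells, 216 genes were at least 2-fold higher and 125 at least 2-fold lower with PINT87aa, out of 15621 genes. Among genes above background on both arrays, the highest difference was in GPD1, the cytosolic glycerol-3-phosphate dehydrogenase that links glycolysis to lipid synthesis, at 2.64. PFKL, the liver form of the glycolytic enzyme phosphofructokinase, was higher by 1.80, the growth factor gene GDF6 by 1.68, and MDFI, an inhibitor of myogenic transcription factors, also by 1.68. Among the lowest values, the antiviral cytidine deaminase APOBEC3G differed by -1.81, complement factor B (CFB) by -1.73, and HCP5, a transcript of the HLA region, by -1.91. FTMT, the mitochondrial ferritin, had the lowest value among genes seen on both arrays, at -2.52.

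Further genes higher in U251 with PINT87aa were CYP27C1 (1.67), F13A1, a coagulation factor subunit (1.64), RFLNB (1.59), the tubulin gene TUBA4A (1.55), ZNF843 (1.54), C5orf46 (1.53), ABO, the blood group glycosyltransferase (1.52), and KIAA0087 (1.51). The lower ones included DOK7, an adaptor of the neuromuscular junction (-2.08), TMEM65 (-1.96), DHRS2 (-1.87), UTF1 (-1.76), ZNF114 (-1.74), PRAMEF8 (-1.72) and GDA, the guanine deaminase (-1.61). The nuclear import gene IPO7 was lower by -2.00 on its chosen probe and by -0.03 on its other probe. Of the genes at least 2-fold different, 154 of those higher and 36 of those lower were above background on 1 of the arrays only. Among these, the muscle gene TNNI2 was at least 7.74-fold higher, the sodium channel SCN7A at least 6.35-fold, the cytokine IL24 at least 4.91-fold and SIGLEC6 at least 3.22-fold. SGCZ was at least 10.1-fold lower, GLOD5 at least 8.27-fold and the oxidase NOX3 at least 4.95-fold. With the normexp background correction 68.4% of the 2-fold genes were lower, against 36.7% with the processed signal.

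Inflammatory genes were lower as a group in U251 cells carrying PINT87aa. The NF-kB and inflammatory list had a median of -0.65, with 17 of 18 measured members below 0, and its median lay below all 10000 random lists of matched expression. ICAM1, a leukocyte adhesion molecule, differed by -1.56 and the cytokine IL1A by -0.99, while the chemokine CCL20 was at least 4.38-fold lower and the growth factor CSF2 at least 1.90-fold lower. Interferon response genes had a median of -0.38, with 26 of 27 below 0, including XAF1 (-1.26), IFITM1 (-1.14) and OAS1 (-0.70), while SAMD9 was higher by 0.56. Immediate early and MAPK feedback genes had a median of -0.46, with 15 of 20 below 0: FOS differed by -1.26, EGR2 by -1.04 and the pathway inhibitor SPRY4 by -0.99. The p53 target list had a median of -0.24 with 19 of 23 below 0, where CDKN1A, the inhibitor of cyclin-dependent kinases, differed by -1.003 and the stress cytokine GDF15 by -0.99, while XPC was at -0.34 and the polymerase POLH at 0.56. All of these medians kept their sign under the 5 other scalings of the arrays.

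Genes of G2 and mitosis and of cholesterol synthesis went the other way in U251, by smaller amounts. The G2 and mitosis list had a median of 0.08 with 36 of 52 members above 0, led by the kinesins CENPE (0.85) and KIF20B (0.60), while the tubulin TUBB4B was at -0.41 and TACC3 at -0.11. The cholesterol synthesis list had a median of 0.17 with 15 of 18 above 0, including the squalene epoxidase SQLE (0.59), DHCR7 (0.30) and MVD (0.04). Neuron markers had a median of 0.31 with 7 of 8 above 0, where NEFM was at least 1.98-fold higher, GAP43 higher by 0.54, MAP2 by 0.32, and DCX lower at -0.35. The matrix and mesenchymal list had a median of 0.16 with 14 of 24 above 0, among them ZEB1 (0.47), with ACTA2 at -0.78; of the U251 arrays, COL1A1 was above background on the PINT87aa array only. With normexp background this median was 0.01 and inside the range. Medians below the random range were also seen for MYC targets (-0.13), the unfolded protein and amino acid response (-0.12), hypoxia and glycolysis (-0.18), heat shock (-0.22) and epithelial markers (-0.34). With quantile normalization MYC targets (-0.08), hypoxia and glycolysis (-0.09) and heat shock (-0.09) were inside the range, as they were with the series table, and so were the unfolded protein list (-0.09) with normexp background, and epithelial markers with the mean of all probes (-0.15) and with no filter on dim probes (-0.43). With random lists not matched on expression, the G2 and mitosis list, MYC targets and the unfolded protein list were inside the range. In all, 13 of the 34 lists lay outside the central 95% of random lists, a description of 1 pair of arrays and not a test.

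The apoptosis lists and the kinases of G1 lay inside the random range in U251 with the main setting. The anti-apoptotic list had a median of -0.08, with XIAP at 0.43, BAG3 at -0.15, BIRC3 at 0.13 and BCL2 at 0.01. The pro-apoptotic list had a median of -0.13, at percentile 3.16 of the random lists, but below the range with normexp background (-0.16), quantile normalization (-0.12), cyclic loess (-0.14), the series table (-0.12) and the mean of all probes (-0.16). Its member BCL2L11 was higher by 1.09 on the chosen probe, while its other probes gave -0.23 and 0.23; HRK was at -0.63, BIK at -0.13 and BAX at -0.12. The G1 cyclins and their kinases had a median of 0.02, the CDK inhibitors 0.10 and the S phase list 0.03. Medians inside the range were also those of growth factor receptors and PI3K (0.07), Notch (-0.10), glioma stem and neural progenitor genes (0.02), astrocyte markers (-0.22), leukocyte markers (-0.06), oxidative phosphorylation (-0.06), autophagy and lysosome (-0.11) and replication-dependent histones (0.11). The medians of NRF2 and metallothionein genes (0.02), Wnt targets (-0.03), cytosolic ribosomal proteins (-0.08), housekeeping genes (-0.05), oligodendrocyte markers (0.17) and transcription elongation genes (0.00) were inside it too, and these 6 changed sign under at least 1 scaling. The autophagy and lysosome median was below the range with normexp background (-0.12) and cyclic loess (-0.11).

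**Figure D1:**
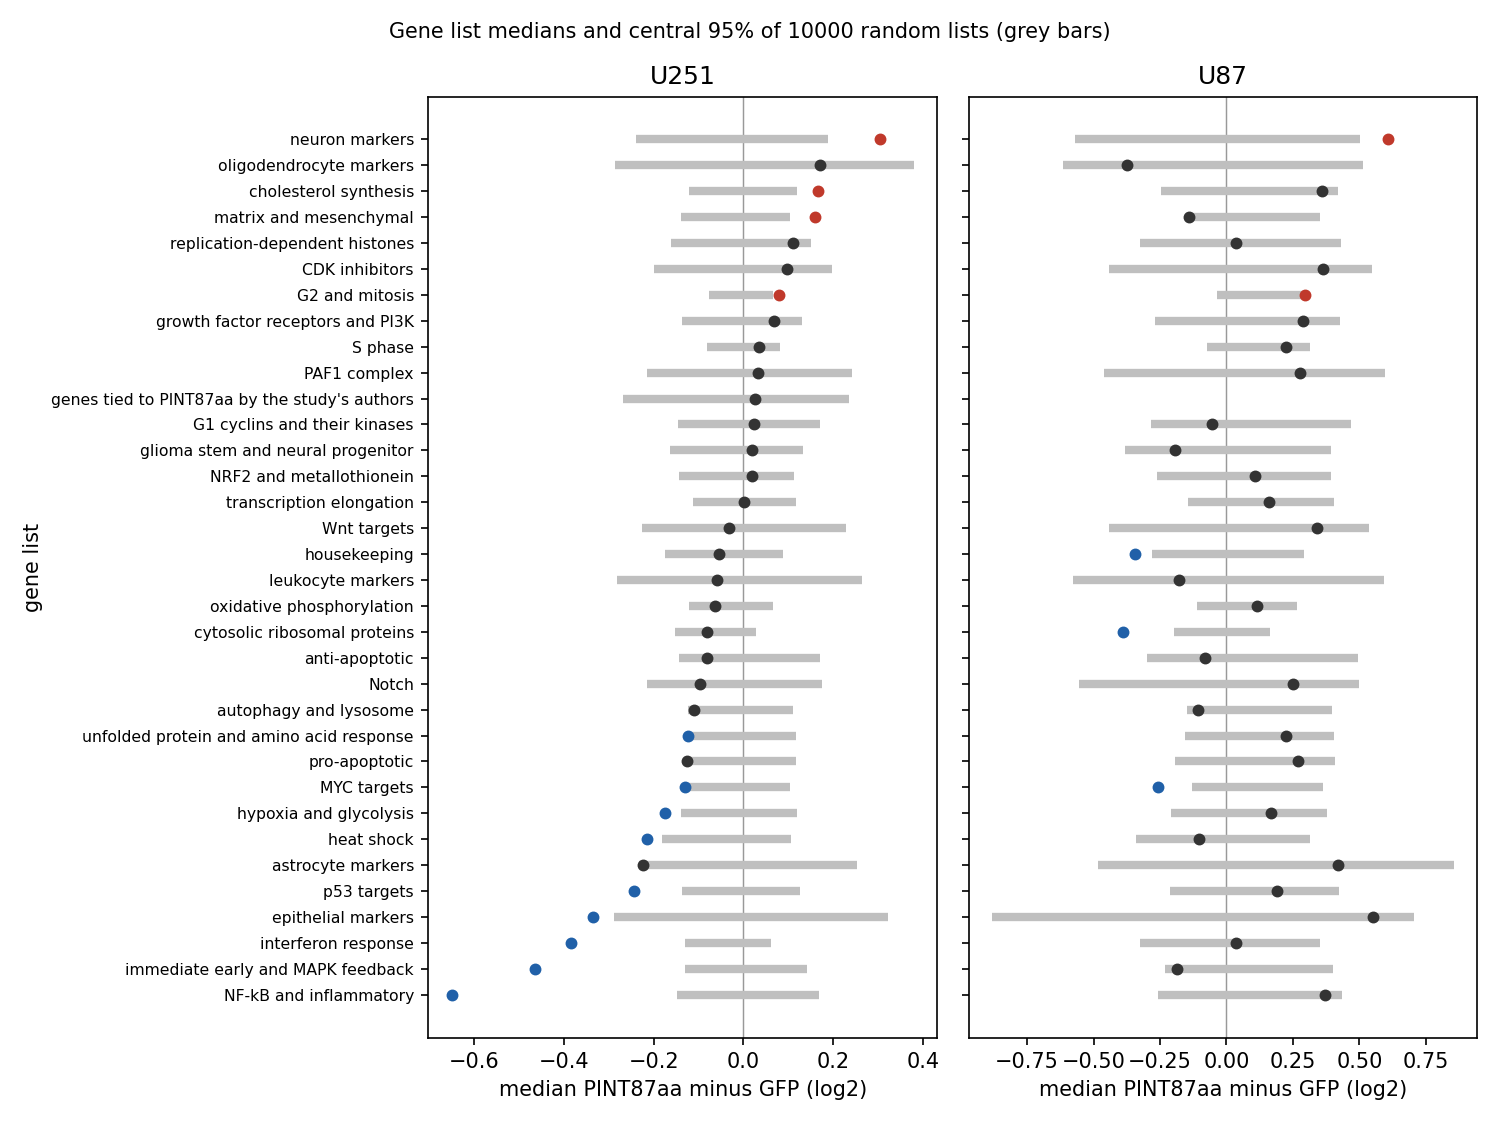
Median PINT87aa minus GFP difference (log2, x axis) of each gene list (y axis) in U251 (left) and U87 (right), 1 pair of arrays each; points are list medians, grey bars the central 95% of 10000 random lists, red and blue points lie above or below it. The NF-kB and inflammatory list sits at -0.65 in U251 and 0.37 in U87, and the cytosolic ribosomal proteins, at -0.39 in U87, turn to 0.05 with quantile normalization.

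Among the genes that the authors' own work ties to PINT87aa, MYC, the growth-promoting transcription factor, differed by -0.03 in U251 and 0.09 in U87. The stem cell factor SOX2 differed by 0.12 in U251 and was near background in U87. The G1 cyclin gene CCND1 differed by 0.08 in U251 and -0.62 in U87. CPEB1, a regulator of mRNA translation, was below detection on the U251 PINT87aa array, at least 39.3-fold lower than with GFP, while in U87 it was higher by 0.51. Its only probe sat in a patch of that array where 8 of 10 bright spots had lost at least 4 log2 units, against 0 of 106 bright spots around them and 0 of the same spots in U87. The patch was drawn around 6 spots already found lost, CPEB1 included, and widened by 1 column. These counts on the U251 array therefore describe the patch and are not a test of it. The list median in U251 was 0.03. Over both lines 0 of its 4 genes passed limma over all genes and 1 passed when adjusted over the list alone; this was CPEB1, and the list, chosen by the authors, is not independent evidence.

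**Figure D2:**
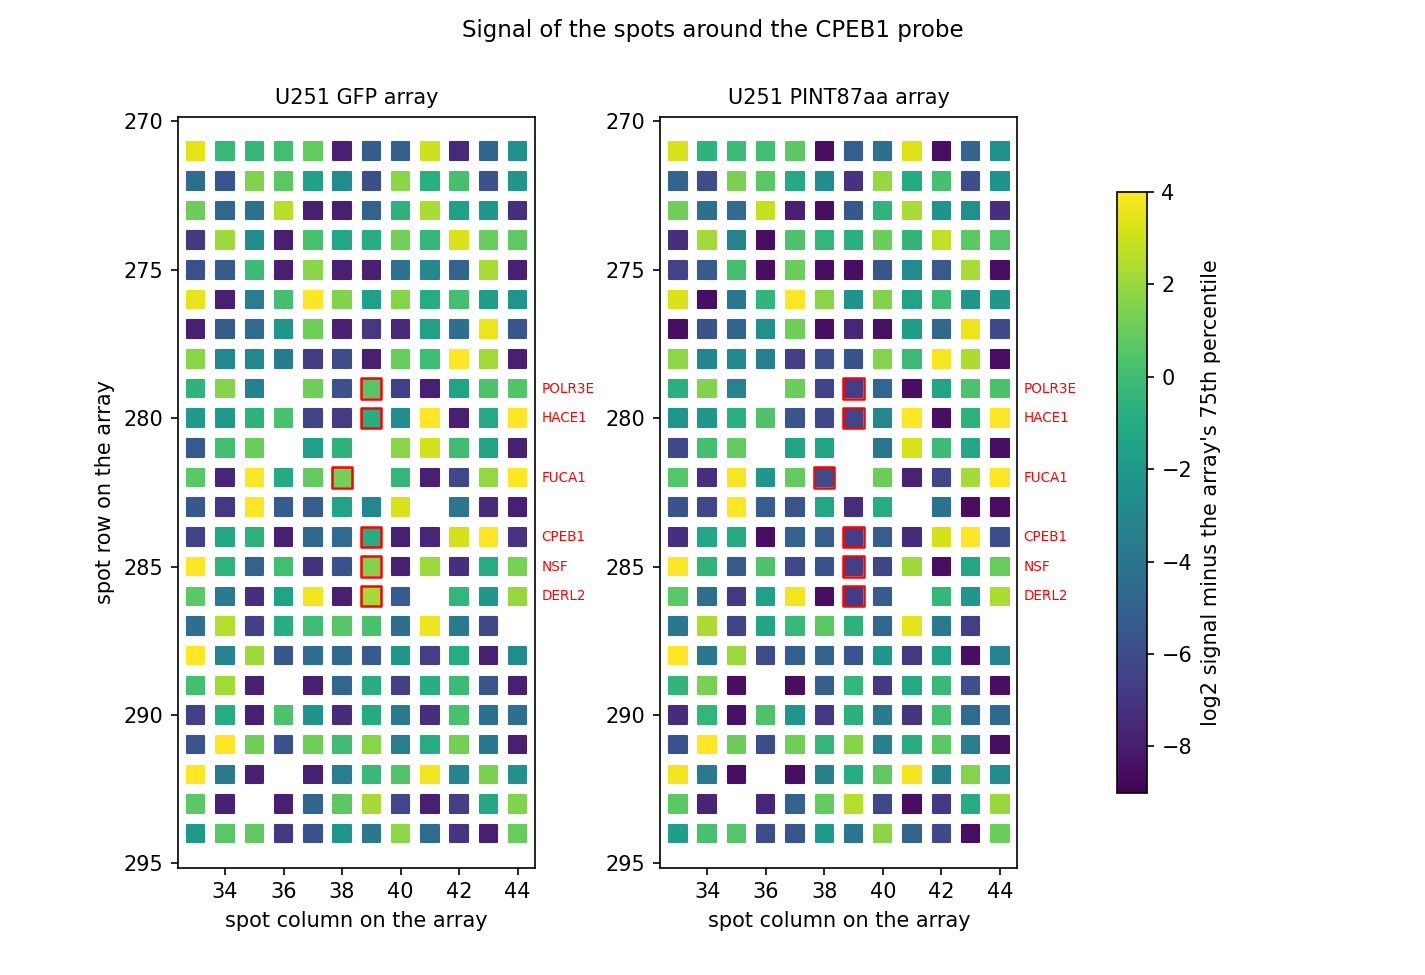
Signal of single spots (colour, log2 minus the array's 75th percentile) by spot column (x axis) and spot row (y axis) around the CPEB1 probe on the U251 GFP array (left) and the U251 PINT87aa array (right). Red boxes mark 6 spots that lost their signal, all in spot rows 279 to 286; blank places are control spots.

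The PAF1 complex, the transcription elongation complex that the authors' work names as the partner of PINT87aa, differed little at the RNA level. Its median was 0.03 in U251 and 0.28 in U87, both inside the random range. PAF1 itself differed by 0.10 and -0.15 in U251 and U87, CTR9 by -0.07 and 0.50, CDC73 by 0.11 and 0.40, LEO1 by 0.00 and 0.15, RTF1 by 0.07 and 0.50, and SKIC8 by -0.49 and -0.26. A second LEO1 probe differed by 0.14 in U251 and -0.43 in U87. LINC-PINT, the host transcript of the circular RNA, differed by -0.11 in U251 and 0.24 in U87, and its neighbour MKLN1 by -0.07 and 0.05. The position of the LINC-PINT probe relative to the PINT87aa reading frame is not given by the sources, so its value does not measure the construct.

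In U87 cells the difference was far broader, with 780 genes at least 2-fold higher and 1140 at least 2-fold lower with PINT87aa, out of 15192. Among the lowest values were MARCKSL1, an actin-binding protein, at -2.91, PARVB of focal adhesions at -2.44, and UBA1, the ubiquitin-activating enzyme, at -2.27. The Janus kinase TYK2 (-2.30), the receptor-like FGFRL1 (-2.36) and the phosphatase regulator PPME1 (-2.28) were lower too. The transporter SLCO2B1 was higher by 2.70, GPD1 by 2.62, the hyaluronan-binding HAPLN2 by 2.46 and the Notch coactivator MAML3 by 2.24, although a second MAML3 probe differed by -0.81.

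Further higher genes in U87 were the glycosyltransferase B3GNT8 (2.42), TMEM65 (2.20), UBE2DNL (2.11), TCF15 (2.04), the homeobox gene SIX6 (2.01) and the protamine PRM2 (1.99). Further lower genes were ZSCAN2 (-2.60), FAM118A (-2.55), PLD3 (-2.47), C21orf58 (-2.44), HYAL4 (-2.34) and TNKS1BP1 (-2.33). Genes above background on 1 array only were 277 of the higher and 42 of the lower, among them PLA2G2A (at least 5.58-fold higher), OR51V1 (3.94-fold), the necroptosis kinase RIPK3 (3.82-fold) and BMP2 (3.57-fold). ACOT12 was at least 6.74-fold lower, RFX6 5.05-fold, AQP6 4.38-fold and HGD 4.21-fold. The first-ranked transcript, RNA28SN5, is the 28S ribosomal RNA: on its chosen probe the U87 GFP array read 2.24 against 6.71, 6.63 and 6.65 on the U251 GFP, U251 PINT87aa and U87 PINT87aa arrays. The U87 GFP array also had the lowest 75th percentile. Lower genes made up 59.4% of the 2-fold genes with the main scaling, 77.3% with normexp background, 48.7% with cyclic loess and 41.3% with median centring, which moved the median difference of genes measured on both arrays from 0.07 to 0.19.

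**Figure D3:**
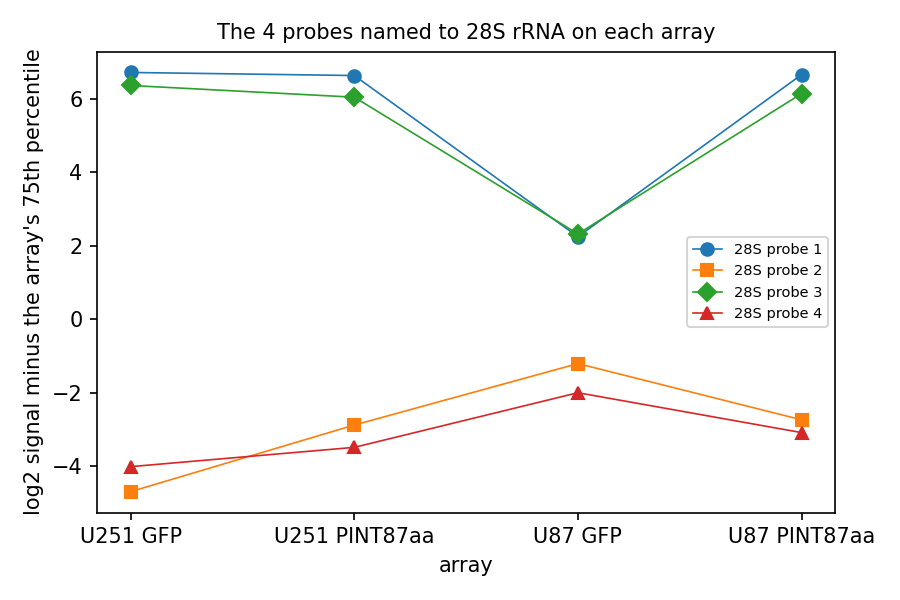
Signal (y axis, log2 minus the array's 75th percentile) of the 4 probes named to 28S ribosomal RNA on each of the 4 arrays (x axis); points are single arrays, and lines join the values of a probe. The upper pair of probes reads 2.24 and 2.32 on the U87 GFP array and between 6.04 and 6.71 on the other arrays, while the lower pair reads highest on the U87 GFP array.

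For genes with several probes, the second probe allowed a check of these differences. In U87 the second probe was also at least 2-fold different the same way for 59 of 277 genes, or 21.3% (exact 95% interval 16.6 to 26.6). In U251 this held for 1 of 20 genes, or 5.0% (exact 95% interval 0.127 to 24.9). The interval covers counting error only. In U87 the second probes of genes named above gave -0.05 for FAM118A, -0.43 for ZSCAN2, -0.57 for C21orf58 and -1.02 for PPME1, and in U251 the other probes of TUBA4A gave 0.64 and 0.43.

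Genes of translation and ribosome building were lower in U87 with PINT87aa under the main scaling. The cytosolic ribosomal proteins had a median of -0.39 with 29 of 30 members below 0, among them RPL11 (-0.72), RPS3 (-0.70) and RPL4 (-0.63), but with quantile normalization their median turned to 0.05, and the deposited series table gave 0.05 too. MYC targets, mostly nucleolar genes, had a median of -0.26: SRM of polyamine synthesis differed by -1.52, and the ribosome assembly factors PES1, NOP2 and BOP1 by -1.48, -1.38 and -1.03. Housekeeping genes had a median of -0.35, with GAPDH at -0.97, PPIA at -0.69 and ACTB at -0.68. Both medians stayed below 0 under the 5 other scalings, but lay inside the range of random lists not matched on expression. All of these groups rest on the U87 GFP array, on which a pair of the 4 probes for 28S read far lower than with PINT87aa (2.24 against 6.65) and the other pair higher (-1.21 against -2.74).

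The G2 and mitosis list was higher in U87, with a median of 0.30 and 37 of 52 members above 0, where KIF20B (0.99) and CENPE (0.81) were again higher and TACC3 (-1.45) and TUBB4B (-1.22) lower. Neuron markers had a median of 0.61 with 6 of 7 above 0, including DCX at least 1.71-fold higher, MAP2 at least 1.46-fold higher and GAP43 higher by 0.73, but their median was -0.03 with the normexp background. These were 2 of the 5 lists outside the random range in U87; the G2 and mitosis list moved inside it with quantile normalization (median 0.23), cyclic loess (0.25), normexp background (0.31) and the series table (0.23), with both other filters on dim probes and with unmatched random lists. The 28S readings of the U87 GFP array stand beside these values too.

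Lists of apoptosis genes, of G1 and S phase genes and of growth factor receptors stayed inside the random range in U87, unlike the G2 and mitosis list and MYC targets. Among anti-apoptotic genes (median -0.08) the chaperone partner BAG3 differed by -1.65, while BIRC3 was higher by 1.46, the caspase inhibitor XIAP by 1.00 and BCL2 by 0.71. A second BCL2 probe gave 0.03. Among pro-apoptotic genes (0.27) BAX was higher by 1.103, HRK at least 2.11-fold and BIK at least 1.32-fold, and BCL2L11 was lower at -0.97, against 0.74 and 0.16 on its other probes; a second BAX probe gave -0.32. The G1 cyclins and their kinases (-0.05) held CDK6 at 1.13, E2F2 at 0.49, CDK2 at -0.73 and CCND3 at -0.98. CDK inhibitors (0.36) held CDKN1C, at least 1.73-fold higher but at -0.01 with normexp background, RB1 at 0.71, CDKN2D at 0.59 and CDKN1A at -0.51. In the S phase list (0.22) FEN1 differed by -1.38, CLSPN by -0.32, USP1 by 0.82 and ATAD2 by 0.68. Among growth factor receptors and PI3K genes (0.29) FLT1 was at least 1.34-fold higher, while KDR differed by -1.32, AKT1 by -1.25 and PDGFRA by -1.07.

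The NF-kB, interferon and p53 lists that were low in U251 lay inside the random range in U87. NF-kB and inflammatory genes had a U87 median of 0.37 and p53 targets of 0.19, where GDF15 was at 0.66 and XPC at -1.16. Interferon response genes had a median of 0.04, which was below 0 with the normexp background (-0.24) and with cyclic loess (-0.01). Immediate early and MAPK feedback genes had a median of -0.19, at percentile 3.79 of the random lists, and were below the range with normexp background (-0.37), quantile normalization (-0.24), cyclic loess (-0.21), the series table (-0.24), the filter on all 4 arrays (-0.27) and the mean of all probes (-0.33). They held ETV4 at -1.33 and SPRY4 at -1.63, with -0.33 on a second SPRY4 probe. The remaining U87 medians inside the range were those of the unfolded protein and amino acid response (0.22), hypoxia and glycolysis (0.17), cholesterol synthesis (0.36), Wnt targets (0.34), Notch (0.25), matrix and mesenchymal (-0.14), glioma stem and neural progenitor (-0.19), oligodendrocyte (-0.37), leukocyte (-0.18) and epithelial markers (0.55). They were also those of NRF2 and metallothionein genes (0.11), oxidative phosphorylation (0.11), replication-dependent histones (0.04) and transcription elongation (0.16). With the mean of all probes the elongation median was -0.26 and below the range, while NF-kB and inflammatory genes (0.37) and cholesterol synthesis genes (0.36) were above it. The matrix and mesenchymal median was below the range with cyclic loess (-0.19), the filter on all 4 arrays (-0.26), no filter (-0.39) and the mean of all probes (-0.38), and Wnt targets were above it with the series table (0.57) and with outlier spots kept (0.59). Astrocyte markers (0.42), heat shock genes (-0.10) and autophagy and lysosome genes (-0.11) changed sign under at least 1 scaling, as did the anti-apoptotic and G1 lists. The differences between the lines in these lists were not tested.

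Across both lines, GPD1 rose with PINT87aa. Its effect in limma, with the cell line as a block, was 2.63 with an SE of 0.35 (adjusted p = 0.00311; higher in 2 of 2 lines), from -4.78 to -2.14 in U251 and from -4.17 to -1.55 in U87. The only other call was a non-coding transcript known by its clone name, FLJ12825, which was near background on both GFP arrays and at least 1.90-fold higher with PINT87aa in U251 and at least 10.0-fold in U87 (adjusted p = 0.00347, computed on the values near background); it lies outside the rule for named genes and was chosen after its values were seen. Limma called 0 genes lower in the main setting. The count depended on the scaling: normexp background gave 29 higher and 73 lower, cyclic loess 88 and 88, median centring 54 and 17, and quantile normalization 5 calls in all. At an unadjusted p under 0.05 there were 1592 genes of 15558, against 373 when the arrays were split crosswise instead of by construct. Adjusted, 2 genes passed by construct and 5 in the crossed split. The residual of each split's fit is the other split, so a shift shared by the PINT87aa arrays raises the first count and lowers the second. The crossed split is thus not an independent chance level. The GPD1 call was lost without the block (adjusted p = 1.00), with no filter on dim probes (0.141) and with trend = FALSE (0.0555). The sources do not say whether the arrays come from separate cultures, and these 2 lines are the only replication. With 1 residual and 20.5 prior degrees of freedom, the variance behind each p-value comes mostly from the other genes. The p-values therefore measure little of a gene's own spread between the lines.

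Few further genes were 2-fold different in the same direction in both lines. There were 32 genes higher in both, against 5.75 for independent lists, and most of those named were dim with GFP: SLC24A5, a melanosome ion exchanger, was at least 2.74-fold higher in U251 and at least 3.11-fold in U87, and LPP at least 2.85-fold and 2.32-fold. MDFI was above background on all 4 arrays and higher by 1.68 and 1.42. DCDC1 was at least 2.14-fold and 2.66-fold higher in U251 and U87, AOC4P at least 1.40-fold and 1.61-fold, and ECSCR at least 1.08-fold and 1.13-fold. ANKRD18A was at least 1.58-fold higher in U251 (1.48 in U87), MPPED1 at least 3.02-fold in U87 (1.43 in U251), and PRAMEF22 differed by 1.67 and 1.79 near background. With normexp background ECSCR (-0.11), PRAMEF22 (-0.27) and ANKRD18A (-0.54) were lower in U87, and DCDC1 in U251 was at -0.01 with the mean of all probes. The 32 genes became 6 with normexp background and 13 with the filter on all 4 arrays. Genes above background on 1 array of a pair were mostly so on the PINT87aa array. In U251 there were 960 of these, against 47 on the GFP array only, and in U87 1093 against 43. Such dim genes can enter the higher lists of both lines through that array, which the number for independent lists does not allow for. Lower in both were 6 genes, against 6.05 for independent lists. They were the interferon-linked UBA7 (-1.39 in U251, -1.16 in U87) and LY6E (-1.13, -1.74), the receptor GPR35 (-1.08, -1.23; its other probe 0.61, -0.37), the claudin CLDN19 (-1.07, -1.96), KRTAP19-5 (-1.05, -1.29) and ZNF735 (-1.001, and at least 2.64-fold lower in U87). Over 14615 genes the lines' differences had a Pearson r of 0.23 and a Spearman rho of 0.30; these run across genes, which are not independent replicates. A further 22 genes were 2-fold different in opposite ways, against 13.0 for independent lists, such as PFKL (1.80 in U251, -1.34 in U87) and TMEM65 (-1.96, 2.20).

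**Figure D4:**
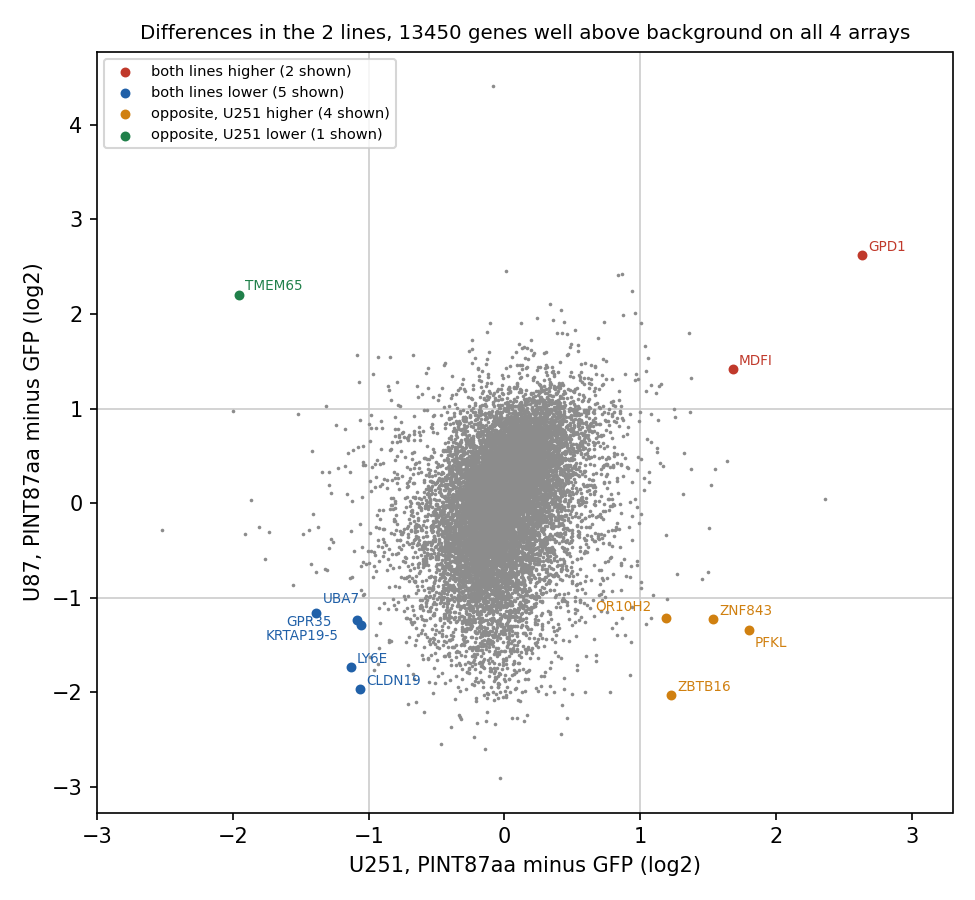
PINT87aa minus GFP difference (log2) in U251 (x axis) and U87 (y axis) for 13450 genes well above background on all 4 arrays; each point is a gene, and grey lines mark 2-fold. GPD1 stands apart at 2.64 and 2.62, and the cloud is wider along the U87 axis than along the U251 axis.

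As groups over both lines, 6 of 34 lists passed limma's camera test with its preset correlation, and 0 passed with an estimated correlation or with fry. Cytosolic ribosomal proteins were lower (median effect -0.21, adjusted p = 5.7e-05), but higher and not called with quantile normalization (adjusted p = 0.625) and with the series table (0.61). Immediate early and MAPK feedback genes were lower (-0.42, adjusted p = 0.00265), as were housekeeping genes (-0.26, 0.00441), interferon response genes (-0.28, 0.0343) and MYC targets (-0.21, 0.0345), while G2 and mitosis genes were higher (0.19, 0.0395). Each of these 6 calls was lost with the estimated correlation (adjusted p = 0.962 with an estimated correlation for each). By line, the interferon list had a median of -0.38 in U251 and 0.04 in U87, where 15 of 26 members were above 0. Under the main scaling its lower level was thus seen in U251 and not in U87. Neuron markers were higher by 0.41 and missed the threshold (adjusted p = 0.0593), which they passed with the mean of all probes (0.0310), as cholesterol synthesis genes did (0.0235). With normexp background ribosomal proteins (adjusted p = 0.102), housekeeping genes (0.12) and MYC targets (0.5) were not called, while cholesterol synthesis genes (higher) and the authors' list (lower, with CPEB1 in the patch of dead spots) were called at an adjusted p of 0.0425. The authors' list was also called with cyclic loess (0.00832) and median centring (0.0146), with the CPEB1 probe in it. Quantile normalization left 1 list past the test, the immediate early and MAPK feedback genes (adjusted p = 0.00111).

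Within these lists 0 members passed over all genes. Adjusted over the list alone, SPRY4 passed as lower among immediate early genes (-1.31), IFITM1 among interferon genes (-0.97), TUBB4B among G2 and mitosis genes (-0.81), and GAPDH, ACTB and PPIA among housekeeping genes (-0.61, -0.46 and -0.44), while 0 ribosomal protein genes and 0 MYC targets passed. In other lists, adjusted over the list alone, CCND3 (-0.78) and CDK6 (0.74) passed among G1 genes, CA9 (-1.36) among hypoxia genes, ACTA2 (-0.91) among matrix genes together with VIM (-0.52), ATP5F1B (-0.67) in oxidative phosphorylation and PECAM1 (1.71) among endothelial markers. The PECAM1 probe was dim on the U87 GFP array, and another PECAM1 probe, above background on both U87 arrays, differed by -0.06. VIM was chosen after its values were seen. Endothelial markers had 3 measured genes, too few for a list test; the others were CDH5 (0.10) and VWF (0.06). Apart from CPEB1 in the authors' list, whose probe lay in the patch of dead spots, 0 members of the lists not named in this paragraph passed in this way.

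The lines themselves differed widely, which sets the scale for the construct. U251 cells carried a strong interferon signature: MX1, an antiviral GTPase, was lower in U87 by -9.73, BST2 by -9.03, OAS1 by -8.68, IFITM1 by -8.62, IFIT1 by -8.21 and IFIT2 by -7.62. The interferon list had a median of -5.32 for U87 minus U251, with 27 of 28 genes called higher in U251 and 1 called higher in U87. NEFL, a neurofilament gene, was lower in U87 by -9.53, CAPS by -8.36, MAGEA6 by -7.69 and IGFBP2 by -7.56. U87 was higher in C1orf94 (8.59), CYP1B1, a xenobiotic-metabolising enzyme (8.37), the cytokine MIF (8.37), FABP5, a fatty acid carrier (8.31), IL1RN, the interleukin receptor antagonist (8.28), EMILIN2 (8.22), MAGEC2 (8.15), CGB3 (7.70), NETO2 (7.34) and SARDH (7.22). Limma called 3023 genes higher in U87 and 3065 higher in U251. Without the U87 GFP array, an alternative chosen after seeing the data that assumes the lone U87 array varies like the others, the counts were 3153 and 3344 of 15220 genes, and 5047 of these calls were also made with all arrays.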

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

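Chosen only after the result was seen were the tests of spot noise, of failed spots and of a loss of CPEB1 transcript in both lines.

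Genes whose difference between PINT87aa and GFP was at least 2-fold in opposite ways in the 2 cell lines were singled out by that contrast; there were 22. The difference between the lines was not tested, because each line has 1 pair of arrays. The glycolytic enzyme gene PFKL differed by 1.80 in U251 and -1.34 in U87, and the zinc finger gene ZBTB16 by 1.23 and -2.03. ZNF843 differed by 1.54 and -1.23, the olfactory receptor gene OR10H2 by 1.19 and -1.21, and ZNF510 by 1.18 and -1.62. In the other direction TMEM65 differed by -1.96 in U251 and 2.20 in U87, PRAMEF8 by -1.72 and 2.15, MIR2052HG by -1.21 and 1.27, IGSF21 by -1.14 and 1.21, and UBD, a ubiquitin-like protein gene, by -1.10 and 1.48. On the U87 GFP array PRAMEF8, IGSF21 and UBD were near background, so in U87 they were at least 1.52-fold, 1.43-fold and 1.13-fold higher; MIR2052HG was near background on 1 array of each line, which bounds it only in U251, at least 1.61-fold lower. ZNF510 was near background on the U251 GFP array and on the U87 PINT87aa array, and in U87 was at least 1.87-fold lower.

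For these opposite genes, chance overlap of the lists cannot be told apart from a real difference, since the observed number was 1.69 times that of independent lists with an exact Poisson interval of 1.06 to 2.56 around a preset bound of 1.5. The U87 GFP value was the one farther from the U251 mean for 86.4% of them (exact 95% interval 65.1 to 97.1), so a U87 GFP array that stands apart may account for many. Over the 1514 U87 2-fold genes well above background on all 4 arrays the share was 73.1%, inside that interval. The opposite genes had no such filter, so the sets are unlike and the comparison does not set the opposite genes apart. With normexp background MIR2052HG (-0.139) and UBD (-0.247) in U87 and ZNF510 (-0.0139) in U251 changed sign, and the 22 genes became 7, or 11 with the filter on all 4 arrays. A response to PINT87aa that differs between the lines stays open and was not tested.

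The broad difference between the U87 arrays, 1920 genes against 341 in U251, is the second pattern. Replicate spots argue against spot noise as the source: the SD over replicate spots in U87 was 0.875 times that in U251, while the spread between genes was 2.41 times as large. Of the 2-fold U87 genes, 1514 were well above background on all 4 arrays. For 73.1% of these (exact 95% interval 70.8 to 75.3) the U87 GFP array was farther from the U251 arrays than the U87 PINT87aa array. Of 115 such genes in U251, 67.0% had the GFP array farther from the U87 mean. Second probes were also 2-fold different the same way for 21.3% of genes in U87 and 5.0% of 20 genes in U251, so that share does not single out the U87 arrays. The SD of the difference between 2 probes of a gene was 0.769 in U87 against 0.341 in U251. It grows with the spread between genes, 2.41 times as large in U87, so it does not single out the U87 arrays either. Across genes the probes' differences had an r of 0.249 in U87 and 0.340 in U251. Part of the broad U87 difference thus lay between probes of the same gene, and its source was not tested. The first share is consistent with a U87 GFP array that stands apart, on which a pair of the 4 probes for 28S read far lower (2.24 against 6.65) and the other pair higher (-1.21 against -2.74). A broad response of U87 to PINT87aa that moved it towards U251 would give the first result too and stays open, untested.

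CPEB1, the translation regulator that the authors' work ties to PINT87aa, lost its signal on the U251 PINT87aa array together with NSF. A loss of the transcript in both lines is argued against by U87, where CPEB1 was higher by 0.512. Failed spots are consistent with the data: 2 of 5350 bright replicate spots failed on that array and 0 on the others, which would give 4.02 failed probes (0.487 to 14.5), and a second NSF probe differed by -0.28 against -8.13. The 6 lost spots lay closer together than every one of 10000 random sets (percentile 0, median distance 29.4 against 1555 position units), so a patch of dead spots may account for the CPEB1 value. Bright spots of the patch that differed by -5.65 and -4.22 were not among these 6. A real loss of CPEB1 in U251 alone was not tested.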

How the results depend on the processing

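Among the alternatives, only the line difference without the U87 GFP array was chosen after the results were seen; its values, 3153 and 3344 calls, stand in the report. Of the counts and summaries that answer a comparison, 119 values under an alternative stayed within 1.5 times the value reported or within its spread and 54 did not. For single genes and lists 3568 stayed so, 379 moved, 22 gained and 25 lost a call, and 13 were marked as changed in sign. These 13 do not hold every change of sign: under at least 1 other scaling the medians of 6 of 34 lists in U251 and 8 of 33 in U87 changed sign. Every cause below was not tested, except where fewer or more genes or a lower threshold make the count smaller or larger by construction.

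With the normexp background there were 30 genes higher and 65 lower in U251 and 265 higher in U87, 6 higher and 3 lower in both lines, 7 in opposite ways, r was 0.342, rho 0.421, and limma called 29 higher and 73 lower. Signs changed, among others, for ZNF510 (-0.0139) and COL1A1 (-0.0661) in U251, and in U87 for ECSCR (-0.112), PRAMEF22 (-0.268), ANKRD18A (-0.540), MIR2052HG (-0.139), UBD (-0.247), CDKN1C (-0.00741) and SLC1A2 (-0.362). In U87 they also changed for the medians of neuron markers (-0.0265) and interferon response genes (-0.241). With quantile normalization rho was 0.288, limma called 2 lower and 12 in the crossed split, 1 list passed camera and the U87 ribosomal protein median was 0.0454; with the authors' series matrix these were 0.287, 2, 14, 1 and 0.0463. Cyclic loess gave 88 limma calls higher and 88 lower. Median centring gave 1208 genes higher in U87 and 54 limma calls higher and 17 lower.

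Restricted to genes well above background on all 4 arrays, 52 genes were higher and 63 lower in U251, 479 higher in U87, 13 higher in both lines and 11 in opposite ways; r was 0.277, rho 0.335, limma called 2 lower and the crossed split 1. With no filter on dim probes 350 were higher and 376 lower in U251, 37 lower in both lines and 61 in opposite ways, rho was 0.317, limma called 0 higher and 1 list passed camera. The mean of all probes gave 1 limma call higher, 10 calls in the crossed split and 10 lists outside the random range in U87, and turned DCDC1 in U251 to -0.00562. At 1.5-fold there were 753 higher and 593 lower in U251, 2928 higher and 2604 lower in U87, 229 higher and 136 lower in both lines and 167 in opposite ways.

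Without the replicate block, that is without the cell line in the model, limma called 0 genes higher, as it did with trend = FALSE. Random lists not matched on expression left 2 lists outside the range in U87. The estimated correlation and fry each left 0 lists past the test. Signal over background limits the lower end: 154 of the 216 genes higher in U251 and 277 of the 780 higher in U87 were above background on 1 array, so their folds are bounds or rest on values near the floor.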

Other observations

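The test of fewer dividing cells was set before its result was seen. The probe comparisons below and the names taken from them were chosen after their values were seen.

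Among genes with several probes above background on both arrays of a line, those with every such probe at least 2-fold different the same way numbered 7 higher and 49 lower of 3309 in U87, and 0 higher and 1 lower of 3472 in U251. The higher U87 genes were the growth factor FGF2, the nuclear pore gene RANBP2, FAM169A, ADAT2, the G protein regulator RGS5, KANK1 and the caspase inhibitor XIAP. The lower U87 genes included CFL1, the actin-severing cofilin, the tumour suppressor MEN1, the interferon regulator IRF3 and the kinase IRAK1. The U251 gene was XAF1, which binds XIAP. Among probes without a gene symbol, 134 were at least 2-fold higher and 76 lower of 4945 in U251, and 375 higher and 418 lower of 4775 in U87.

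In U87 the difference ran with expression level: the median was -0.25 in the decile of lowest expression, 0.24 in decile 9 and 0.11 in the highest. The U251 medians had the same shape at a smaller size: -0.11 in the lowest, 0.02 in decile 9 and -0.03 in the highest. Across 13450 genes the U87 arrays had a Pearson r of 0.969 and the U251 arrays one of 0.993. The U87 GFP array had an r of 0.875 with each U251 array, and the U87 PINT87aa array 0.893 with U251 GFP and 0.902 with U251 PINT87aa.

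A hypothesis was that the PINT87aa cultures held fewer dividing cells, which would lower the G2 and mitosis genes in both lines. The test gave no sign of it: the lower of the medians in the 2 lines was 0.0782, above 0, against a preset bound of -0.1. The CDK inhibitors do not add to this. CDKN1A, an inhibitor of division, was lower by -1.003 in U251 and -0.51 in U87. Of the list, however, 6 of 9 members were above 0 in U251 (median 0.10) and 8 of 9 in U87 (median 0.36). RNA levels of these genes do not measure the division rate.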
